A study of Cucumis melo with 30 samples.

How the data were processed

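The series holds RNA sequencing of oriental melon fruit from 2 cultivars at 5 days after anthesis, with 3 libraries in each of 10 groups. Per the labels' protocols, fruit was frozen in liquid nitrogen, total RNA was taken with Trizol and cDNA libraries were made by a standard Illumina procedure. The labels describe no enrichment or depletion step, strand or read length. HISAT2, an aligner, and HTSeq, a read counter, are named in the submitters' processing notes, without versions. The genome build, the annotation and the counting options are not given in the sources used here. The authors deposited 1 table of raw read counts per gene, whole numbers that sum to 17299247 to 23261097 per library, with 27427 gene identifiers and 30 columns, all of them used. No row stood for unassigned reads.

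Identifiers were looked up in a table of 28628 melon genes made from the assembly USDA_Cmelo_AY_1.0, and 0 of the 27427 matched. No gene names, functions or coordinates are therefore given, and the gene lists fixed before the data were examined, for pathways such as carotenoid, ethylene, sugar and aroma metabolism and for tissue markers, could not be applied. Genes that share reads with near-identical copies or with overlapping or antisense neighbours could not be recognised, so each identifier's count may include or lack such reads.

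Columns were assigned to samples by their titles, and groups were taken from the labelled strain and developmental stage. The labels do not say whether the 3 libraries of a group came from separate fruits or plants, so p-values measure the spread between these samples, which may be technical in part. No batch or date is given. All replicate pairs were compared before averaging: none was identical, and chi-square statistics per degree of freedom lay between 7.35 and 118 (genes with a summed count of at least 20), so each library was counted as its own sample.

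Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes were kept by filterByExpr with the groups (minimum count 10, minimum total count 15), which left 18426. Library sizes were scaled by TMM, and a model with a mean for each of the 10 groups was fitted to all 30 libraries, which share 1 estimate of the spread. Robust dispersion estimation gave a biological coefficient of variation of 19.1% and 4.08 prior degrees of freedom. Quasi-likelihood F tests were run for YMR minus HDB at each day, for the later minus the earlier day over each step and from day 5 to day 35 within each cultivar, and for the difference of these changes (YMR minus HDB), and a joint F test covered all interaction terms. Genes at a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called, and all tests were two-sided unless stated. Standard errors of log2 fold changes were obtained as the absolute log2 fold change over the square root of F. The 4 interactions over single steps were added after the first counts had been seen.

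CPM values are deposited counts per 1000000 of the TMM-scaled library size. Where all libraries of a group had no count, the fold change is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with an exact conditional binomial interval at 95%. Intervals and floors cover counting error only. Principal components were computed on log2 CPM with a prior count of 2. Overlaps between lists of called genes were set beside the overlap of independent lists of the same sizes. Comparisons set against each other in this way share no library.

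The genes named in the text were chosen by a rule fixed before the data were examined. For the cultivars they are those called with the same sign at all 5 days and with the largest mean log2 difference, for the steps and the whole span those called with the same sign in both cultivars and with the largest mean change, and for the interaction those with the largest difference in the day 5 to day 35 change. A mean of at least 10 CPM in at least 1 group was required. The rule asked for a product name, and for 2 identifiers per direction and comparison where no table gives names, as here. MELO3C024771 is also described as the most counted gene.

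Alternatives chosen before the data were examined were size factors of the RLE type in place of TMM, DESeq2 1.42.0 in place of edgeR, no low-count filter, the replicate number as a block, only the compared groups in the fit, an added threshold of 2-fold, and each library of the compared groups left out in turn. Scaling by total counts alone was added after the TMM factors had been seen. The block was not part of the chosen model, since nothing in the labels says that equal numbers mark a shared fruit, plant or day.

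The test for day 25 was checked on counts simulated from the groups' means, library sizes and dispersions. Both day 25 groups were given their average mean, and 200 genes without low counts were then changed, equally up and down. Over 4 simulations of 18267 to 18290 genes the test recovered 36% of the genes changed 1.5-fold and 78% of those changed 2-fold. It recovered 94.5% at 4-fold and 99.5% at 8-fold, and 34 of 650 calls (5.23%) were false. The real day 25 comparison called 48.3% of genes, with mean TMM factors of 0.969 in HDB and 0.759 in YMR. The simulations had few changed genes and hardly any difference in composition, so they do not check the scaling there. A first simulation alone had given 15 false calls of 164 (9.15%), after which the number was raised to 4; it is among the 4.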

Results

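RNA was sequenced from fruit of oriental melon, a thin-skinned type of Cucumis melo grown mainly in East Asia. The submitters' labels name 2 cultivars, HDB-OF and YMR-WF (HDB and YMR from here on), and 5 days after anthesis, the opening of the flower: days 5, 15, 25, 30 and 35. Each of the 10 combinations of cultivar and day had 3 libraries, 30 in all. Total counts lay between 17299247 and 23261097 per library. Of 27427 genes in the deposited table, 5517 had no read in any library, and 18426 passed the low-count filter and were tested. Levels are given as CPM, counts per 1000000 of the TMM-scaled library size, as mean ± SD over the 3 libraries of a group (n = 3). Genes carry only their identifiers, because the sources used here do not pair these with names or positions.

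The number of genes with at least 10 counts fell as the fruit aged, from 17222 ± 32 at day 5 to 15117 ± 162 at day 35 in HDB and from 17249 ± 115 to 15135 ± 107 in YMR. A single gene, MELO3C024771, came to take the largest share of the counts in both cultivars. At day 5 it held 0.00072% ± 0.00051 of the counts in HDB and 0.00031% ± 0.000091 in YMR. From day 25 on it was the most counted gene in every group, with 2.09% ± 0.086 of the counts in HDB and 1.2% ± 0.078 in YMR at day 25, and 1.83% ± 0.12 and 2.4% ± 0.24 at day 35. The 10 most counted genes together held 4.38% ± 0.35 of the counts at day 5 and 7.59% ± 0.25 at day 35 in HDB, against 5.36% ± 0.6 and 10.6% ± 0.6 in YMR. TMM factors, which correct for differences in composition, averaged 0.969 in HDB and 0.759 in YMR at day 25, the widest gap between the cultivars at any day. At that day the 10 most counted genes held 7.93% ± 0.14 in HDB and 5.97% ± 0.47 in YMR. The lower factor of YMR thus did not go with a larger share for its most counted genes.

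Libraries separated mainly by day. The first principal component of log2 CPM held 60.5% of the variance and ran from the day 5 libraries, at -195.4 or lower, to the day 30 and day 35 libraries, at 104.1 or higher. On this component the day 25 libraries of HDB lay between 89.7 and 96.7, and those of YMR between 37.5 and 65.5. The second component, with 10.5% of the variance, also changed with the day. In HDB it went from between 52.6 and 68.9 at day 5 to between -58.2 and -45.5 at day 15. It set the cultivars apart from day 15 on but not at day 5. Correlations of log2 CPM between libraries of a group ranged from 0.963 to 0.992.

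**Figure D1:**
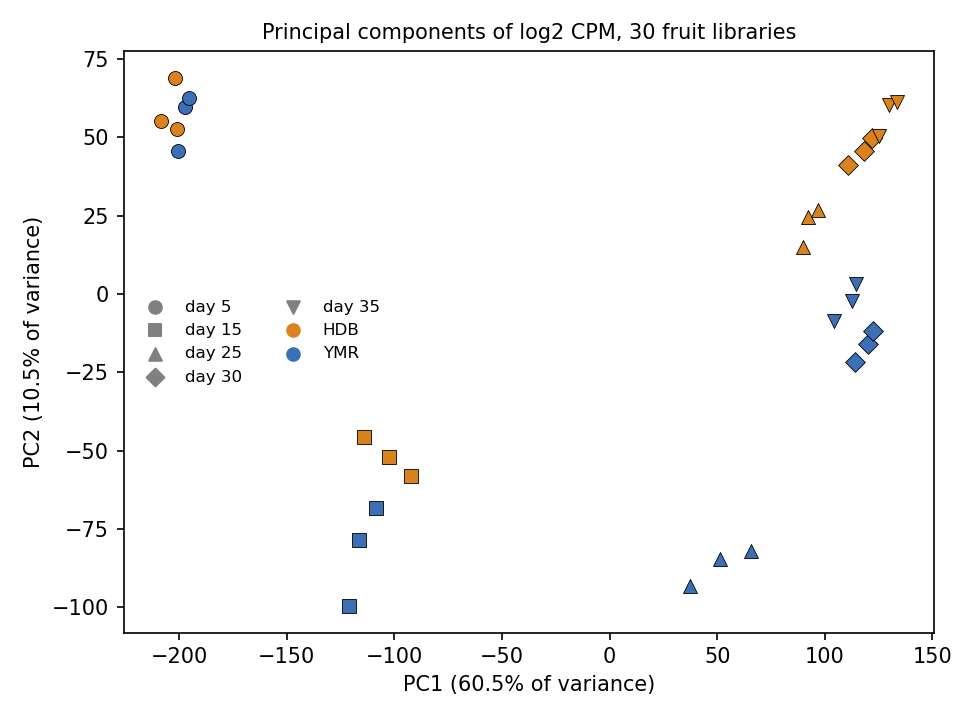
First and second principal components of log2 CPM (60.5% and 10.5% of the variance, arbitrary units), 1 point per library, with colour for the cultivar and shape for the day. The day 5 libraries of both cultivars lie together at the left, and the 3 YMR libraries of day 25 lie apart, at 37.5 to 65.5 on the first axis and -93.1 to -82 on the second.

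The first question was how the 2 cultivars differed at each day. Some genes were read in only 1 of them at every day sampled. MELO3C012644 had no count in any HDB library, while in YMR it stood at 10.2 ± 1.9 CPM at day 5, 21.6 ± 3.7 at day 25 and 1.69 ± 0.78 at day 35. It was at least 215-fold higher in YMR at day 5, at least 456-fold at day 25 and at least 33-fold at day 35, set against a floor of 3 counts over the HDB group (edgeR adjusted p = 1.6e-06, 3.7e-08 and 3.3e-05). MELO3C001286 showed the mirror image, with no count in any YMR library and 28 ± 3.9 CPM at day 5 falling to 7.15 ± 2 at day 35 in HDB. It was at least 675-fold lower in YMR at day 5 and at least 128-fold lower at day 35 (edgeR adjusted p = 1e-09 and 4.3e-09). No count in a group of 3 libraries allows a level of up to 0.041 to 0.067 CPM, depending on the group.

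MELO3C003990 peaked at day 15 in HDB, at 1990 ± 790 CPM, and had 352 ± 84 CPM at day 5 and 24 ± 4.6 at day 35. In YMR it had 23 counts at day 15 (0.347 ± 0.14 CPM) and none at the other 4 days. Its log2 difference, YMR minus HDB, was -12.46 (SE 0.47, edgeR adjusted p = 9.5e-11) at day 15, and it was at least 8460-fold lower in YMR at day 5. MELO3C000680 was the other gene named as higher in YMR, where it rose from 71.3 ± 29 CPM at day 5 to 331 ± 43 at day 25 and stood at 109 ± 34 at day 35. In HDB it had 2.49 ± 2.4 CPM at day 5, where 1 library had 1 count and the others up to 101. The log2 difference was 4.84 (SE 0.54, edgeR adjusted p = 1.3e-06) at day 5. At day 25 the HDB libraries held 2 counts of it, and the ratio of YMR to HDB was 10400 with an exact 95% interval of 2880 to 85900 for counting error.

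These 4 genes headed a set of 180 that differed in the same direction at all 5 days, 86 of them higher and 94 lower in YMR, where independent lists of the observed sizes would share 4.2 and 3.7. Most differences were not of that kind. In all, 15671 of the 18426 genes passed the test on at least 1 day, 4594 of them on exactly 1 day, and 4995 were higher in YMR on 1 day and lower on another.

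At day 5, 4012 genes differed, 1918 higher and 2094 lower in YMR, and 1438 of the 4012 differed at least 2-fold. Day 15 gave 7537 genes (3765 higher, 3772 lower, 2826 at least 2-fold) and day 25 gave 8893 (4903 higher, 3990 lower, 4364 at least 2-fold). The number dropped to 6159 at day 30 (3124 higher, 3035 lower, 2474 at least 2-fold) and was 8784 at day 35 (4328 higher, 4456 lower, 3886 at least 2-fold). The plot of called genes shows these counts beside those of the steps. With only the 6 libraries of a day in the fit, day 5 gave 2529 genes and day 15 gave 3459, and without replicate 3 of HDB day 5 the day 5 count was 2667. In the 6-library fits the set sharing a direction at all 5 days had 46 higher and 55 lower genes. The low-count filter changed with the libraries there, and 14412 genes passed it in all 5 fits. Scaling by total counts alone gave 2239 higher and 1597 lower at day 5, 3682 and 3462 at day 15, 2874 and 7138 at day 25, 1696 and 5439 at day 30, and 3173 and 5539 at day 35, and moved the median log2 difference of all genes from 0.03 to -0.28 at day 25 and from 0 to -0.23 at day 30. At day 35 RLE size factors gave 4793 higher and 4055 lower, so on no day was the larger direction the same under every alternative.

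**Figure D2:**
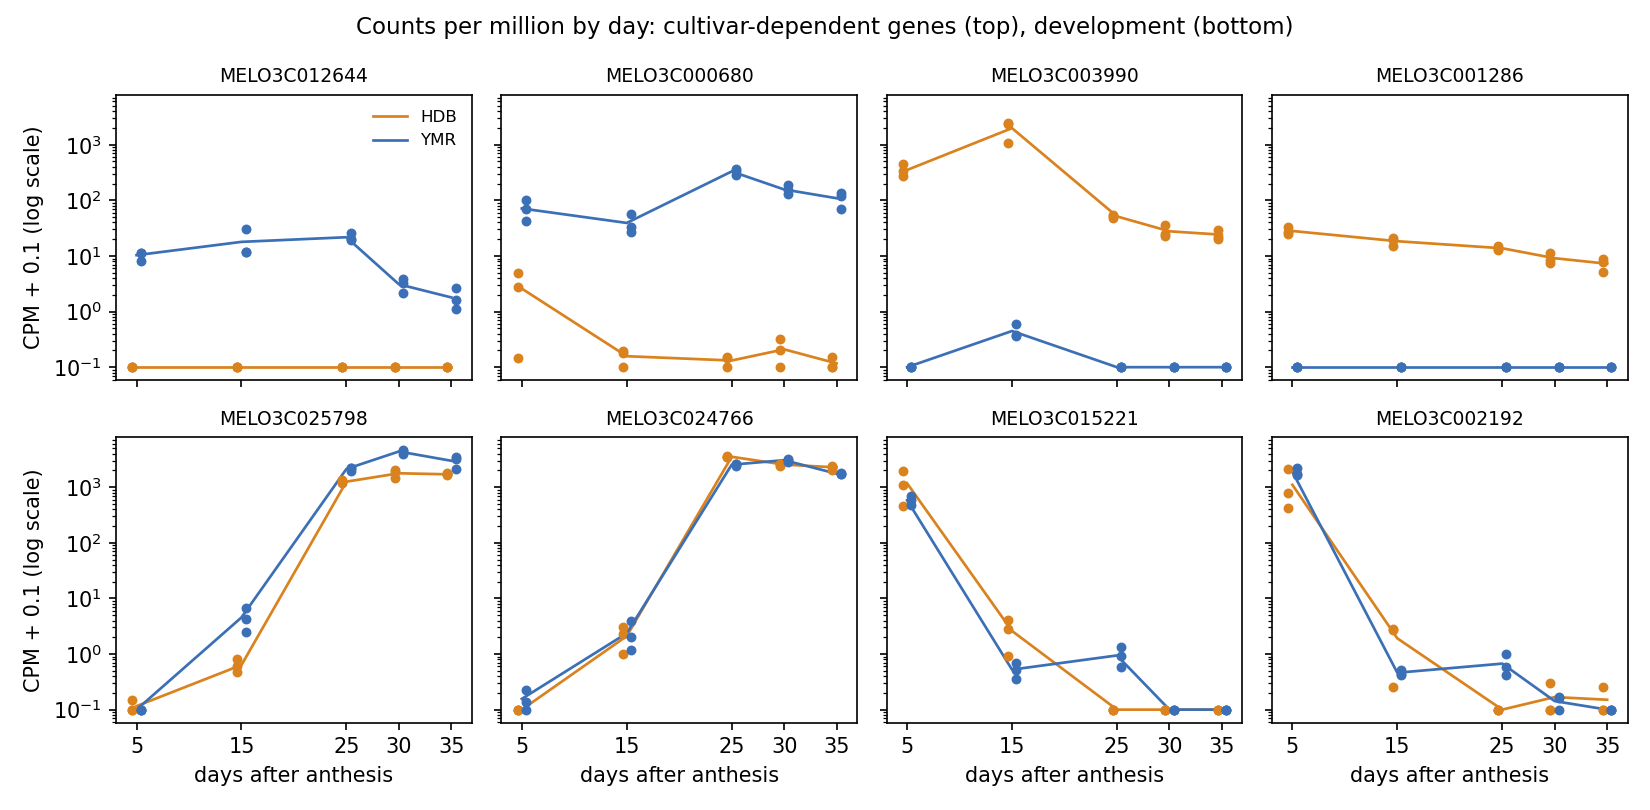
CPM plus 0.1 on a log scale against days after anthesis for the 4 genes named for the cultivars (top) and the 4 named for the change from day 5 to day 35 (bottom), with 1 point per library (n = 3 per group), lines through the group means and orange for HDB, blue for YMR. MELO3C012644 stays at 0 in HDB and MELO3C001286 at 0 in YMR at all 5 days, while the bottom genes move together in both cultivars by day 35.

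The second question was how the fruit changed with age. Between day 5 and day 35 some transcripts appeared or vanished in both cultivars. The genes named here were chosen for a shared direction, so their agreement follows from the rule. MELO3C025798 went from 1 count in the HDB libraries and 0 in the YMR libraries of day 5 to 1700 ± 70 and 2980 ± 730 CPM at day 35, at least 71800-fold higher in YMR and by a ratio of 107000 (exact 95% interval 19200 to 4220000) in HDB. MELO3C024766 rose from no count to 2270 ± 160 CPM in HDB, at least 47300-fold, and from 0.0561 ± 0.067 to 1750 ± 56 CPM in YMR, a log2 change of 14.79 (SE 0.54, edgeR adjusted p = 2.9e-16). MELO3C015221 fell from 1170 ± 770 CPM in HDB and 583 ± 100 in YMR at day 5 to no count at day 35, at least 22300-fold and 10300-fold lower (edgeR adjusted p = 5.8e-09 and 1.4e-08). MELO3C002192 fell from 1900 ± 310 CPM to no count in YMR, at least 33800-fold, and from 1100 ± 880 CPM to 3 counts in HDB, by a ratio of 20900 (exact 95% interval 7160 to 101000).

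Across the whole span 14609 genes changed in HDB, 6666 up and 7943 down, with 10042 changed at least 2-fold. In YMR 13887 changed, 6097 up and 7790 down, with 9127 changed at least 2-fold. Large changes ran mostly downward by the fitted values: 2554 genes fell and 432 rose at least 16-fold in HDB, against 2168 and 476 in YMR. A count of 3 or fewer at day 5 and a mean of at least 10 CPM at day 35 in both cultivars was found for 17 genes, and the reverse for 148. The cultivars shared 4817 genes that rose and 6354 that fell, where independent lists would share 2206 and 3358. In opposite directions 696 genes moved, against 5446 for independent lists. Across genes, which are not independent replicates, the log2 changes of the 2 cultivars correlated at r = 0.873. Under total-count scaling the YMR balance was 4129 up and 9869 down, and the median log2 change of all genes moved from -0.19 to -0.59 in YMR and from -0.15 to -0.34 in HDB.

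**Figure D3:**
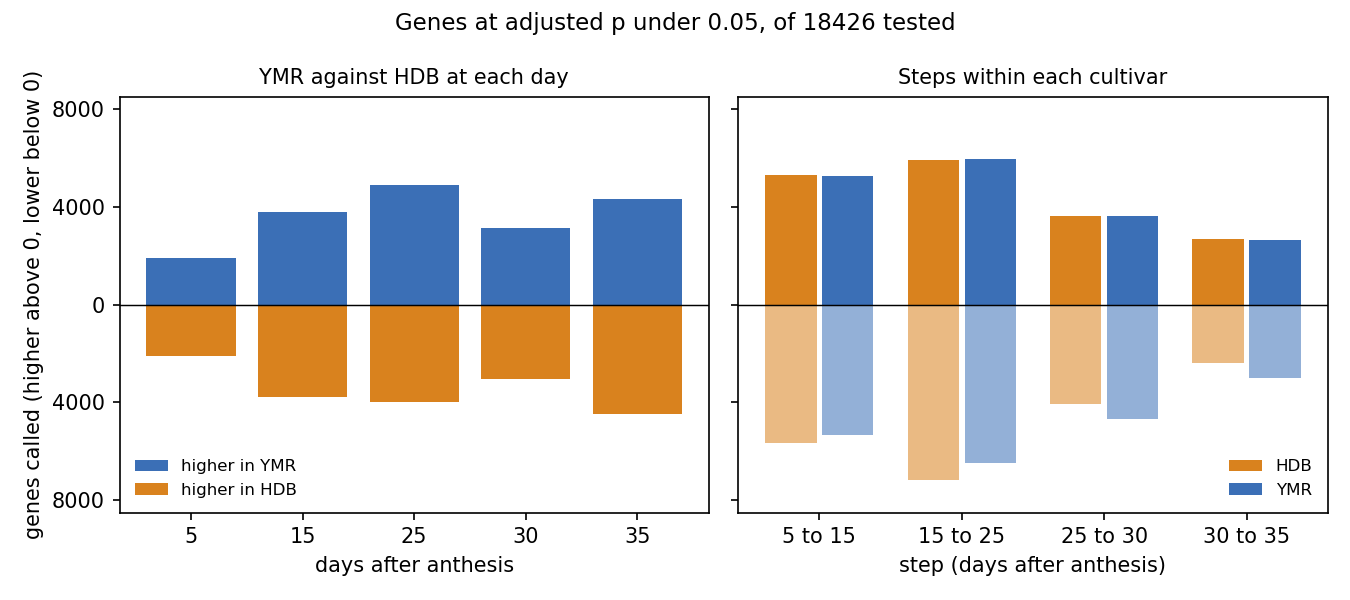
Number of genes at an adjusted p under 0.05 (vertical axis, higher above and lower below 0) for YMR against HDB at each day (left, blue for genes higher in YMR and orange for genes higher in HDB) and for each step between days within HDB (orange) and YMR (blue), with falling genes in the lighter shade (right). The step from day 15 to day 25 has the most genes in both cultivars, 13083 in HDB and 12421 in YMR.

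From day 5 to day 15, MELO3C013366 rose from 1 count in the HDB libraries to 164 ± 120 CPM, by a ratio of 10500 (exact 95% interval 1880 to 414000), and from 0.0866 ± 0.15 to 480 ± 160 CPM in YMR, a log2 change of 12.38 (SE 0.64, edgeR adjusted p = 4.2e-13). It went on to 3790 ± 130 and 3050 ± 340 CPM at day 25. MELO3C018536 rose over the same step to 18.3 ± 4.9 CPM in HDB and, at least 1190-fold, to 50.2 ± 16 in YMR, and at day 35 stood at 3.7 ± 0.48 and 3.91 ± 2. MELO3C021150 stood at 279 ± 59 CPM in HDB and 204 ± 81 in YMR at day 5 and had no count in any later library, at least 6890-fold and 4610-fold lower at day 15. MELO3C025369 went from 551 ± 180 CPM to no count in HDB, at least 13600-fold lower, and from 217 ± 110 CPM to 1 count in YMR. In HDB 10948 genes changed (5299 up, 5649 down, 5590 at least 2-fold) and in YMR 10582 (5252 up, 5330 down, 5301 at least 2-fold). The cultivars shared 2982 rising and 3287 falling genes, 853 moved in opposite directions (325 with only the compared groups in the fit), and r across genes was 0.711. Independent lists from the fit to all libraries would give 1510 rising, 1634 falling and 3143 opposite genes.

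The step from day 15 to day 25 held the rise of MELO3C024771, from 3.09 ± 2 to 21600 ± 1100 CPM in HDB and from 3.25 ± 1.5 to 15900 ± 1800 in YMR. Its log2 changes of 12.76 (SE 0.59) and 12.25 (SE 0.58) did not differ detectably between cultivars (edgeR adjusted p of the difference = 0.48). MELO3C010779 rose from 0.219 ± 0.21 to 301 ± 68 CPM in HDB and from 2 counts to 285 ± 160 CPM in YMR. MELO3C023361 fell from 185 ± 170 CPM to no count in HDB, at least 3910-fold, and from 97.3 ± 28 CPM to 3 counts in YMR, by a ratio of 1440 (exact 95% interval 494 to 7000). MELO3C004098 fell from 32.7 ± 9.5 and 16.5 ± 3 CPM to no count in either cultivar, at least 679-fold and 244-fold lower. Both cultivars had their highest step count here, 13083 genes in HDB (5904 up, 7179 down, 7992 at least 2-fold) and 12421 in YMR (5964 up, 6457 down, 7227 at least 2-fold). Shared genes numbered 3955 up and 4736 down, with 982 opposite and r = 0.694 across genes. For independent lists the numbers would be 1911, 2516 and 4393. With total-count scaling YMR had 2940 up and 10235 down, the shared rising genes numbered 1941, and the median log2 change of all genes moved from -0.07 to -0.66 in YMR and from -0.13 to -0.36 in HDB.

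From day 25 to day 30, MELO3C002175 rose from 6.96 ± 2.1 to 482 ± 26 CPM in HDB, a log2 change of 6.12 (SE 0.32, edgeR adjusted p = 4.4e-12). In YMR it rose from 16.2 ± 1.8 to 114 ± 43 CPM (log2 change 2.81, SE 0.27) and reached 646 ± 96 CPM at day 35. The change of this step differed between cultivars by -3.3 on the log2 scale (SE 0.38, edgeR adjusted p = 1.2e-06). MELO3C010433, with no count before day 25 in either cultivar, rose to 1.14 ± 0.32 CPM in HDB and 10 ± 2.8 in YMR at day 30. MELO3C007559 fell from 20.7 ± 2.2 to 0.143 ± 0.15 CPM in YMR, a log2 change of -7.11 (SE 1.21), and MELO3C026932 fell from 40.2 ± 18 to 0.358 ± 0.22 CPM, a log2 change of -6.81 (SE 0.96). In HDB these 2 genes had 0.893 ± 1.4 and 0.758 ± 0.92 CPM at day 25 and no count at day 30, and were called there at an edgeR adjusted p of 0.021 and 0.049. Both HDB calls were lost without replicate 3 of HDB day 25 (0.4 and 0.27), which held 53 of 56 and 38 of 48 counts and without which the fitted log2 changes, no bounds, went from -7.16 to -3.63 and from -6.93 to -5.27. They were also lost without any single library of HDB day 30 (0.052 to 0.06 and 0.097 to 0.11), where the fitted changes stayed at -7.16 and between -6.94 and -6.93. The HDB call of MELO3C026932 was also lost without the low-count filter (0.068) and with the replicate number as a block (0.054). Altogether 7694 genes changed in HDB (3630 up, 4064 down, 2802 at least 2-fold) and 8290 in YMR (3614 up, 4676 down, 3674 at least 2-fold). Both cultivars shared 1588 rising and 1776 falling genes, 708 were opposite (1091 with only the compared groups in the fit), and r fell to 0.36. Independent lists from the fit to all libraries would give 712 rising, 1031 falling and 1718 opposite genes. Total-count scaling turned the balance, to 3846 up and 3585 down in HDB and 4922 up and 3664 down in YMR.

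The last step, day 30 to day 35, was the one in which the cultivars had least in common. MELO3C025995 rose in both, from 1.45 ± 0.26 to 5.51 ± 3.6 CPM in HDB (log2 change 1.93, SE 0.51, edgeR adjusted p = 0.0062) and from 1.9 ± 0.15 to 36 ± 22 CPM in YMR (4.24, SE 0.51, edgeR adjusted p = 2.4e-06). Without replicate 1 of HDB day 35 its HDB call was lost (log2 change 1.24, edgeR adjusted p = 0.087). In YMR this gene had already stood at 20.6 ± 4.8 CPM at day 25, above its day 30 level. MELO3C003138 rose from 0.428 ± 0.2 to 3.04 ± 0.53 CPM in HDB and from 1 count to 0.808 ± 0.13 CPM in YMR, far below its 33.2 ± 23 and 48.6 ± 29 CPM of day 5. MELO3C005947 fell from 1.69 ± 0.57 to 0.0927 ± 0.073 CPM in HDB and from 2.79 ± 1.6 to 0.317 ± 0.12 in YMR (log2 changes -4.15, SE 0.85, and -3.1, SE 0.65). MELO3C012992 fell from 0.432 ± 0.034 CPM to 1 count in HDB and from 7 counts to none in YMR, where it was at least 2.54-fold lower. The YMR calls of MELO3C003138 and MELO3C012992 (edgeR adjusted p = 0.023 and 0.033) were lost without some single libraries, replicates 1 and 2 of day 30 and replicate 3 of day 35 for the former (0.08, 0.07 and 0.053), and replicates 2 and 3 of day 30 and each of the 3 of day 35 for the latter (0.07 to 0.083). The fitted log2 changes, which at such counts depend on the prior count, were 4.92 for the former and 4.46, 4.46 and 4.83 without those libraries, and -4.58 for the latter and -4.33 to -4.59. In HDB 5064 genes changed (2692 up, 2372 down, 1710 at least 2-fold) and in YMR 5639 (2640 up, 2999 down, 1678 at least 2-fold). In both cultivars 234 rose (151 without replicate 2 of HDB day 30) and 438 fell, against 386 and 386 for independent lists, while 1443 moved in opposite directions against 778, and r across genes was 0.041. The balance turned with RLE size factors, to 2497 up and 2580 down in HDB and 2896 up and 2749 down in YMR, and in YMR also with total-count scaling, to 3434 up and 1986 down.

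Patterns over all 4 steps, with each step scored as a rise, a fall or no call, were the same in both cultivars for 2597 genes (14.1%), where independent patterns would give 542. The most frequent shared pattern was a fall from day 5 to day 15 with no later call (416 genes), followed by falls over the first and second steps (394) and a fall over the second alone (347). In 338 genes no step was called in either cultivar.

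The third question was whether the change over time differed between the cultivars, tested as an interaction. The 2 genes named with the largest difference toward HDB rose in HDB and all but vanished in YMR. MELO3C011865 went from 48 ± 7.2 CPM at day 5 through 686 ± 47 at day 25 to 318 ± 100 at day 35 in HDB, and in YMR from 50.3 ± 19 through 2.81 ± 1.2 to a single count. MELO3C007153 followed the same course, from 55.2 ± 8.6 to 319 ± 140 CPM in HDB and from 46.9 ± 16 CPM to a single count in YMR. The day 5 levels did not differ detectably between cultivars (edgeR adjusted p = 0.92 and 0.7), and the day 5 to day 35 changes did (edgeR adjusted p = 5.1e-11 and 3.5e-10). In the other direction, MELO3C027040 fell from 8.46 ± 5.4 CPM to no count in HDB, at least 160-fold, and had 1.96 ± 0.87 CPM at day 5 and 4 ± 3.6 at day 35 in YMR, a change that did not pass the test there (edgeR adjusted p = 0.11, of the difference 4.9e-06). MELO3C000631 had 167 ± 48 CPM at day 5 in HDB and no count there from day 25 on, at least 3130-fold lower at day 35. In YMR it had 3 counts in all, in a single day 35 library. Its interaction (edgeR adjusted p = 0.0026) rested on those counts: without replicate 1 of YMR day 35 the adjusted p was 1, and with DESeq2 it was 0.13.

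Over the whole span the change differed between cultivars for 6630 genes, with a more positive change in YMR for 3241 and in HDB for 3389, and by at least 2-fold for 3702. Total-count scaling gave 2203 and 4726, RLE size factors gave 3560 and 3080, and total-count scaling moved the median log2 difference of all genes from 0.02 to -0.19. Step by step the numbers were 6406 genes from day 5 to day 15 (3269 more positive in YMR, 3137 in HDB, 3280 at least 2-fold), 7629 from day 15 to day 25 (4225 and 3404, 4223 at least 2-fold), 5527 from day 25 to day 30 (2520 and 3007, 2940 at least 2-fold) and 6106 from day 30 to day 35 (2874 and 3232, 2993 at least 2-fold). For the first step, a fit to its 12 libraries alone gave 4028 genes, and for the step from day 15 to day 25 total-count scaling gave 2369 and 5857, with a median of -0.31 in place of 0.04. The larger direction also turned with total-count scaling in the other steps, to 2834 and 3208 from day 5 to day 15, 2935 and 2355 from day 25 to day 30, and 3267 and 2518 from day 30 to day 35, and with RLE size factors to 3115 and 3292, 2805 and 2708, and 3168 and 2911. A test of any interaction over the 5 days was passed by 13713 genes, 74.4% of those tested.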

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

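A test of the difference itself found that the 2 cultivars changed differently over time for the genes given here. The step interactions, the second way of judging a deviating library, the checks for exchanged labels and for low counts and the criterion for regrouped libraries were chosen after the results they concern had been seen.

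The change from day 5 to day 35 differed between the cultivars for 6630 genes. Over the single steps it differed for 6406 genes (day 5 to 15), 7629 (day 15 to 25), 5527 (day 25 to 30) and 6106 (day 30 to 35), and any interaction was called for 13713. The libraries were also regrouped, in 40 ways for each interaction with the real grouping among them. The day 5 to 35 interaction gave 6296 genes for its own 12 libraries and at most 4328 for another grouping, and the single steps gave 4028 against 1905, 6602 against 3228, 6698 against 4927 and 6997 against 4376. The joint test gave 13713 against 4516. In each of these 6 cases only 1 of the 40 groupings, the real one, gave as many genes, a share under 0.05. The regrouping reassigned cultivar labels within each day, so the other groupings mixed the cultivars. Any cultivar difference, also one constant over days, then adds to the spread within groups. The share therefore speaks against no cultivar difference of any kind, and cannot exclude chance for the interaction alone.

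Among the named genes, MELO3C011865 and MELO3C007153 rose in all 3 HDB libraries of day 35 relative to day 5 (log2 changes 2.73, SE 0.35, and 2.53, SE 0.38), and in YMR they fell to 1 count, by ratios of 2620 (exact 95% interval 471 to 104000) and 2450 (439 to 96600). The adjusted p of the difference was 5.1e-11 and 3.5e-10 (edgeR). MELO3C027040 differed the other way (edgeR adjusted p = 4.9e-06), with a fall of at least 160-fold to no count in HDB and 1.96 ± 0.87 and 4 ± 3.6 CPM at days 5 and 35 in YMR. MELO3C000631 also passed (edgeR adjusted p = 0.0026), on 3 counts in YMR at day 35. Its call was lost without replicate 1 of YMR day 35 and with DESeq2 (DESeq2 adjusted p = 0.13). MELO3C002175 rose more in HDB from day 25 to day 30 (difference -3.3, edgeR adjusted p = 1.2e-06), and MELO3C010433 more in YMR (3.01, edgeR adjusted p = 0.029). From day 30 to day 35, MELO3C025995 rose more in YMR (2.31, edgeR adjusted p = 0.014). There it had stood at 20.6 ± 4.8 CPM at day 25 and 1.9 ± 0.15 at day 30. Its call in HDB was lost without replicate 1 of HDB day 35.

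The first pattern weighed is that YMR at day 25 lay nearer to its own day 15 than HDB did. Over 9082 genes that changed the same way from day 15 to day 35 in both cultivars, with 0 for a cultivar's day 15 mean and 1 for its day 35 mean, HDB stood at 0.782 ± 0.013 and YMR at 0.669 ± 0.059 (n = 3, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). Ranks within libraries, which no scaling factor changes, gave a difference of 0.142 against 0.113. By ranks the lowest HDB library stood at 0.818 and the highest YMR library at 0.727. These values argue against scaling as the only cause, over genes that were chosen under TMM. Total-count scaling kept 72.3% of the difference, between the bounds set in advance, so an effect of scaling on its size stays open. A single deviating library stays open too: without replicate 1 of YMR day 25 the difference kept 74.4% of its size, and the criterion first written, a gap between the groups (0.041) smaller than the range within a group (0.118), did point to such a library before it was replaced. That YMR fruit at day 25 were at an earlier point of the same course cannot be told apart from these: the day 25 difference, YMR minus HDB, correlated with the day 15 to 35 change at r = -0.25 across genes, but projected on that change it was -0.161 over the 9082 genes, so the correlation largely restates the positions (difference -0.113). The positions at day 30 had the other order, 0.913 ± 0.02 in HDB and 0.962 ± 0.019 in YMR.

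The second pattern is that from day 30 to day 35 genes called in both cultivars more often moved in opposite directions than in the same one, at a ratio of 2.15. The tables argue against scaling as the cause, as the ratio was at least 1.89 under RLE and total-count scaling, and against a deviating library, as it was at least 1.95 without each of the 12 libraries. An exchange of the day 30 and day 35 labels cannot be told apart in either cultivar: in HDB the day 30 mean resembled 3 of the 3 earlier groups more (r higher by 0.016, 0.021 and 0.002 with days 5, 15 and 25), with the libraries of the 2 days apart for days 5 and 15 and overlapping for day 25, and in YMR it did so for 1 of 3 (0.017 with day 25, libraries apart), with overlap for days 5 and 15 (-0.01 and -0.001). YMR may have passed this part of its course a sampled step later. Its day 30 to 35 change correlated with the HDB day 25 to 30 change at r = 0.22 across genes. Over the alternatives r was 0.16 to 0.25, so under the bound of 0.2 in some. Of the genes called in both, 2498 agreed in sign against 609. The reverse pairing gave r = 0, with 990 and 1579 genes. The agreement partly restates the pattern, because the HDB day 30 libraries enter both HDB changes with opposite signs. A shift of those libraries alone would make the same step look opposite and the lagged pair agree. It therefore cannot decide on a delay. Correlations of group means were also compared for a delay of YMR. YMR at day 35 resembled HDB at day 30 more than at day 35 (r = 0.96 and 0.947). So did every earlier YMR group, from day 5 (0.697 and 0.681) to day 30 (0.959 and 0.946). The order at day 35 thus does not speak for a delay. Against a delay, YMR at day 30 resembled HDB at day 30 more than at day 25 (0.959 and 0.944). YMR at day 25 likewise resembled HDB at day 25 more than at day 15 (0.922 and 0.839). By the positions of the first pattern YMR was ahead at day 30 (0.962 against 0.913). Growth conditions, for which the labels give nothing, stay untested.

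The third pattern is the 180 genes that differed in the same direction at all 5 days. For well-counted genes the tables argue against low counts as the cause of the shared direction. Among the 10399 genes with a mean of 10 CPM or more in both cultivars, 44 were higher and 43 lower in YMR at all 5 days. Independent lists would share 7.1 and 3.8, and the observed genes were 8.01 times as many. Over all tested genes the excess was larger, 86 higher and 94 lower against 4.2 and 3.7. For the members with a lower mean in a cultivar, low counts stay open. Blocks of neighbouring genes missing or diverged in a cultivar relative to the reference cannot be told apart from other differences: no coordinates were available, and 6 pairs of neighbouring tested rows of the count table, whose order is not shown to follow position, were in the set, against a median of 2 in 10000 random draws (permutation p = 0.007, one-sided), but as many genes with the largest change over time gave 9 such pairs. Neighbouring rows outside these pairs, seen after the test, were MELO3C003990 and MELO3C003993, nearly or fully silent in YMR, and MELO3C025948 and MELO3C025947, nearly or fully silent in HDB. Variants that keep reads of 1 cultivar from aligning may act gene by gene and were not tested.

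For the comparisons of 3 libraries against 3, there are 10 groupings, too few for a share under 0.05. In all 15 of them 1 of the 10, the real one, gave the most genes, and the highest of the others was 0. With only the compared libraries in the fit the real groupings gave 2529, 3459, 9354, 6524 and 8863 genes between cultivars at days 5, 15, 25, 30 and 35. The steps gave 8766, 11886, 9006 and 5657 in HDB and 8217, 10838, 8207 and 6194 in YMR, and day 5 to day 35 gave 13886 in HDB and 12836 in YMR.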

How the results depend on the processing

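Total-count scaling and the step interactions were chosen after the data had been seen. Of 325 alternative values for the counts of genes, 302 stayed within 1.5 times and 23 did not. With an added 2-fold threshold the counts were 1438, 2826, 4364, 2474 and 3886 between cultivars at days 5, 15, 25, 30 and 35, 5590, 7992, 2802 and 1710 for the HDB steps, 5301, 7227, 3674 and 1678 for the YMR steps, 9127 for YMR from day 5 to day 35, 3702 for the interaction over that span and 3280, 4223, 2940 and 2993 for the step interactions, all lower because fewer genes can pass. With only the compared groups in the fit, day 5 gave 2529, day 15 gave 3459 and the day 5 to 15 interaction 4028, while other counts rose, such as 9354 at day 25, 6524 at day 30 and 9006 for HDB from day 25 to 30; the cause was not tested. Leaving out single libraries gave 2667 to 3760 genes at day 5, the lowest and only one beyond 1.5 times without replicate 3 of HDB day 5, and left all other counts within 1.5 times. Which direction had more genes turned under at least 1 of total-count scaling, RLE size factors, DESeq2, the block or fits of the compared groups for the cultivar comparison at every day, for the steps from day 25 to 30 and 30 to 35 in both cultivars and for all 5 interactions between days, and under none of these for day 5 to 15, 15 to 25 and 5 to 35 within either cultivar. Overlaps moved too: total-count scaling gave 1941 shared rising genes in place of 3955 from day 15 to day 25, and fits of the compared groups changed the opposite genes from 853 to 325 (day 5 to 15) and from 708 to 1091 (day 25 to 30), and the genes sharing a direction at all 5 days to 46 and 55. Without replicate 2 of HDB day 30, 151 genes rose in both cultivars over the last step. Of 788 alternatives for the named genes 767 kept the call and direction, 21 lost the call and none reversed. Lost calls fell on 6 of 64 results: MELO3C007559 and MELO3C026932 (day 25 to 30, HDB), MELO3C003138 and MELO3C012992 (day 30 to 35, YMR), MELO3C025995 (day 30 to 35, HDB) and the interaction of MELO3C000631. With the replicate number as a block, counts such as 8799 at day 25 stayed close to those without it, and only MELO3C026932 lost its call (adjusted p = 0.054). Equal numbers showed no general pairing of the samples. Deviations of same-numbered libraries correlated at a mean of -0.005, against 0.002 for different numbers, and in 0 of 15 comparisons were all pairs over 0.1. Between cultivars the pairs gave 0.31, 0.03 and 0.15 at day 5 and -0.16, -0.01 and 0.18 at day 15. Pairing of single libraries or within a day is therefore not excluded. The gene list tests were not run, as identifiers had no names, and the joint interaction test has no 2-fold or compared-groups value. Depth limits groups without counts to levels under 0.041 to 0.067 CPM.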

Other observations

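Beyond MELO3C012644, 3 genes were at 3 counts or fewer over all HDB libraries while a YMR group averaged at least 10 CPM. They were named after their values had been seen. MELO3C025948 and MELO3C025947 had 1583 and 1118 counts over the YMR libraries and 1 and 0 over the HDB libraries, with highest group means of 22.9 and 15.3 CPM. MELO3C005212 had 1120 counts in YMR and 2 in HDB. The reverse held for 10 genes, among them MELO3C001286 and MELO3C000631, the latter with 10456 counts in HDB and 3 in YMR. Another was MELO3C003993 (3290 counts in HDB, none in YMR), the row after MELO3C003990 in the count table, whereas MELO3C003992 (7878 and 1), whose identifier falls between theirs, lay elsewhere in it. MELO3C025948 and MELO3C025947 were also neighbouring rows.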
